A study of Mus musculus with 6 samples.

How the data were processed

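RNA was sequenced from the whole spinal cords of 6 mouse embryos at E13.5, of strain C57BL/6J per the labels. Of these, 3 carried the genotype NFIA-ff and were labelled control, and 3 carried NFIA-ff with Nestin-cre and were labelled NFIAcKO. RNA was prepared on RNeasy columns and libraries with an Illumina stranded mRNA kit, per the labels' protocols. The submitters' processing notes name STAR 2.6.1a, HTSeq, DESeq2 and the mm10 build, without saying which step each served. The deposited values are whole-number counts per gene symbol, 1 file per library, not normalized. The annotation release and the strand setting of the counting are not given in the sources used here, so the counts of genes that overlap another on either strand are uncertain. Beyond those said to overlap where they are named, these include Nfic, Nfix, Vmn2r57, Myh7b, Cubn, Fbn2, Olig1, Nkx2-2, Hk1, Lss, Bax, Higd1a, Jun and Col9a3.

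Each file held 55433 genes and 5 summary lines of the kind HTSeq writes. Those lines were kept out of library sizes and tests. They made up 16.9 to 19.4% of a file's total, of which 3.75 to 4.62% of the total were reads assigned to no gene. Reads that matched several genes made up 4.18 ± 0.0429% (SD, n = 3) in the libraries labelled control and 3.97 ± 0.0622% in those labelled NFIAcKO. Reads aligned to several places made up 9.96 ± 0.561% and 9.04 ± 0.0985%. The counts assigned to genes summed to 43393053, 51465763 and 45544664 in control replicates 1, 2 and 3, and to 48947073, 48405312 and 47388945 in NFIAcKO replicates 1, 2 and 3. At these depths a count of 0 in a library allows up to 3 counts, which is 0.0583 to 0.0691 CPM on library totals without TMM scaling, for counting error only. Within a group, every pair of libraries differed by more than sampling noise, with a chi-square per degree of freedom of 10.9 to 45.3, so all 6 were counted as separate samples.

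The groups were compared in edgeR 4.0.16 under R 4.3.3 by the robust quasi-likelihood F test with TMM scaling. The filter filterByExpr kept 17711 genes. A gene was said to rise, fall or change at a Benjamini-Hochberg adjusted p under 0.05, and adjusted p values given for genes are edgeR's unless another tool is named. Fold changes are libraries labelled NFIAcKO over those labelled control, with the standard error (SE) on the log2 scale, and CPM (counts scaled to library size) are on TMM-scaled library sizes except where said. The SE of a gene is the one implied by the F test, the absolute log2 fold change over the square root of F. The biological coefficient of variation was 11.5%. On simulated counts for the same 17711 genes and 3 against 3 libraries, with 200 genes changed, the test recovered 61% of 1.5-fold and 81% of 2-fold changes, and 8.97% of its calls were genes that had not been changed. A gene length trend of 0.0993 on the log2 scale per doubling, put into unchanged simulated libraries, gave 11 calls, and 1 call once it was removed. That is smaller than the slope of 0.13 in the data over genes with a mean log2 CPM over 1, so it does not give the calls that the trend in the data would make.

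Before the data were examined, 35 gene lists were fixed, covering neuronal and glial programs, metabolism, stress and markers of other cell types that a dissected cord could hold. Of these, 34 were tested with camera in limma 3.58.1, on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists. The 5 sex-linked genes were kept as values only. Each list was also tested with its correlation estimated from the data, under which no list passed, and 2 lists had an unadjusted p under 0.05. The directional fry test called 6 lists: NFI family, ventral interneurons, axon guidance and microglia, the tricarboxylic acid cycle and fatty acid oxidation. Members of each list were also adjusted over the list alone. The rule for named genes, fixed at the same time, took the 4 NFI genes, the 10 largest rises and 10 largest falls among changed genes with at least 1 CPM in the higher group and no overlap between groups (leaving out predicted Gm and Rik genes and sex-linked genes), up to 4 members of each list by smallest p, and the sex-linked genes. Slc1a2, Uchl1, Cxcr4, Glra2, Hes5, Ppargc1a and Apcdd1, and members named because few of their list moved, were chosen after their values were seen. Results of some genes that the rule names are not reported here.

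Gene length, GC content, coordinates and overlaps came from the GENCODE annotation M21 of GRCm38, the assembly that mm10 names. It matched 53642 symbols by name, and 98.8% of tested genes had a length and GC value. The length here is the summed length of all annotated exons of a gene, and GC content is that of its longest transcript. After the data were seen, a trend with length and GC was removed from each library by natural splines of 5 degrees of freedom, fitted on genes with a mean log2 CPM over 1 and entered as offsets, and all tests were repeated. Each list's median was also set among 10000 random lists of equal size, matched in deciles of length and expression.

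The alternatives tried were DESeq2 1.42.0, limma-voom, RLE and upper quartile scaling, no filter on low counts or 1 CPM in at least 3 libraries, the replicate number as a block, the number that file names share as a block, Xist as a covariate, leaving out globin, mitochondrial, X-inactivation and Y-linked genes, a glmTreat test against a fold change of 1.2 (its value for Nfia was not kept), and leaving out each library in turn.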

Results

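Gene expression was measured in whole spinal cords of mouse embryos at E13.5, a day of gestation when motor neurons have been born and the formation of glia is beginning. The series compares 3 embryos labelled control (NFIA-ff) with 3 labelled NFIAcKO (NFIA-ff with Nestin-cre), to ask what the transcription factor NFIA does in the development of motor neurons. Nestin-cre is a transgene that expresses cre recombinase in neural progenitors, and NFIA is best known for its part in the onset of glial development. Counts assigned to genes ranged from 43393053 to 51465763 per library. By Xist and Y-linked genes, both groups held embryos of both sexes. Xist reached 342 CPM in control replicate 2 and 192 CPM in NFIAcKO replicate 2, and at most 0.0633 CPM in the other 4 libraries, where Ddx3y stood at 44.0 to 54.2 CPM (on library totals without TMM scaling). Only the embryos labelled NFIAcKO carried cre, so the transgene and the deletion were not separated by the design, and the labels give no litters.

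Nfia itself was higher, not lower, in the libraries labelled NFIAcKO. Its mean level was 66.1 ± 11.4 CPM (SD, n = 3) in the libraries labelled control and 111 ± 7.02 CPM in those labelled NFIAcKO, a log2 fold change of 0.75 (SE 0.11, adjusted p = 0.0031). The counts were 2641, 3110 and 3683 in control replicates 1 to 3 and 5144, 5016 and 5636 in NFIAcKO replicates 1 to 3, so all 3 libraries labelled NFIAcKO lay above all 3 labelled control. Nfia (ENSMUSG00000028565.18) lies on chromosome 4 of GRCm38 from 97772734 to 98118874 on the plus strand, with 10891 bp of annotated exons. A count over the whole gene includes exons that remain after recombination, so it does not test the deletion. E130114P18Rik overlaps it by 4 bp on the opposite strand. Because the higher Nfia count does not bear out the label, groups are called by their labels throughout, and every direction given is relative to those labels. Among the other NFI genes, Nfic rose by 1.29-fold (adjusted p = 0.034), while Nfib and Nfix differed by 0.06 and 0.02 on the log2 scale (adjusted p = 0.71 and 0.92). The NFI list as a set was not called by camera (2 of 4 members rose, also 2 when adjusted over the list alone, camera adjusted p = 0.14), but was by the fry test (adjusted p = 0.048). The Nfic call held only when control replicate 3 was left out among the 6 such fits. It was lost without control replicates 1 and 2 (adjusted p = 0.128 and 0.13) and without NFIAcKO replicates 1, 2 and 3 (0.14, 0.064 and 0.115), and when the length and GC trend was removed (0.118).

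**Figure D1:**
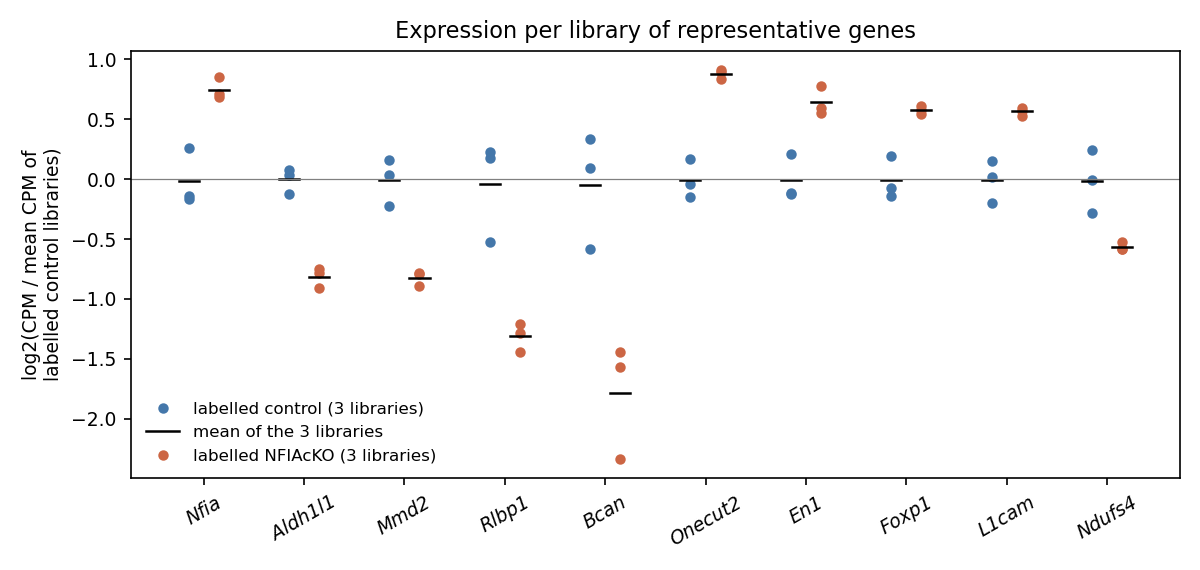
Expression of 10 genes in each of the 6 libraries, as log2 of CPM over the mean CPM of the 3 libraries labelled control; each point is a library and each line the mean of the 3 values of a group. Nfia stands at a higher level in all 3 libraries labelled NFIAcKO, and Aldh1l1, Mmd2, Rlbp1 and Bcan at a lower one.

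Across the transcriptome, 2468 of 17711 genes changed, of which 1392 were higher and 1076 lower in the libraries labelled NFIAcKO, a label that the Nfia count does not bear out. Most changes were small. The median size among changed genes was 0.41 on the log2 scale, 11 genes rose and 46 fell by over 2-fold, and 128 rose and 220 fell by over 1.5-fold. Groups did not overlap for 33.4% of tested genes, where chance gives 10%. With upper quartile scaling the split was 1057 higher and 1434 lower (42.4% higher, against 56.4%), and a test against a fold change of 1.2 called 27 and 14. The counts moved with each library left out. They were 282 higher and 220 lower without control replicate 1, 700 and 412 without control replicate 2, 2703 and 2466 without control replicate 3, 312 and 139 without NFIAcKO replicate 1, 599 and 431 without NFIAcKO replicate 2, and 325 and 150 without NFIAcKO replicate 3.

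Long transcripts were higher and short ones lower in the libraries labelled NFIAcKO. The median log2 fold change rose from -0.23 among genes in the octile with the shortest exonic length, where 7 genes rose and 249 fell, to 0.21 in the octile with the longest, where 720 rose and 21 fell. Genes that rose had a median exonic length of 8840 bp and genes that fell 2424 bp, against 3976 bp for all tested genes. The slope of log2 CPM per doubling of length, relative to the mean of the libraries, was -0.0645, -0.117 and -0.0188 in control replicates 1 to 3 and 0.0674, 0.0396 and 0.0931 in NFIAcKO replicates 1 to 3. With the length and GC trend removed, 676 genes were higher and 686 lower. Of the original calls, 517 rises and 460 falls remained, and no gene was called in opposite directions.

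**Figure D2:**
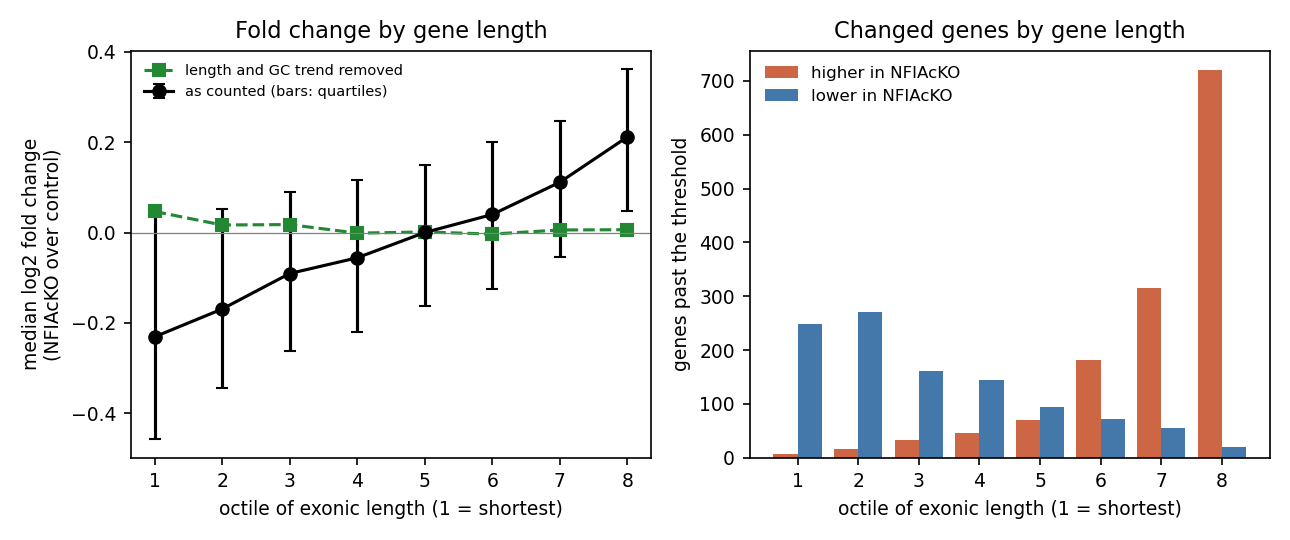
Left, median log2 fold change (NFIAcKO over control, as labelled) of genes in 8 bins of exonic length, as counted with quartiles as bars and with the length and GC trend removed; right, the number of genes past the threshold per bin. The median goes from -0.23 in the shortest bin to 0.21 in the longest as counted, and 720 genes rose in the longest bin.

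Astrocyte genes were lower in the libraries labelled NFIAcKO for part of the list. Of 24 tested members, 9 fell, 1 rose and 14 did not pass, and when adjusted over the list alone 9 fell and 3 rose. Aldh1l1, a folate enzyme used as a pan-astrocyte marker, fell from 64.4 ± 4.59 to 36.7 ± 2.09 CPM (SD, n = 3; log2 fold change -0.81, SE 0.09, adjusted p = 0.0008). Mmd2 fell from 33.8 ± 4.45 to 19.1 ± 0.822 CPM (-0.82, SE 0.11, adjusted p = 0.0025), and Hopx by 0.76 on the log2 scale (adjusted p = 0.0068). These 3 kept their calls in all 6 fits that leave out a library and with the trend removed, although Aldh1l1 and Hopx overlap other annotated genes. Aldoc, an aldolase of astrocytes that the glycolysis list also holds, fell from 143 ± 42.1 to 59.3 ± 8.77 CPM (adjusted p = 0.032). That call held only without control replicate 3, and was lost without control replicates 1 and 2 (adjusted p = 0.0804 and 0.187), NFIAcKO replicates 1, 2 and 3 (0.0846, 0.0615 and 0.0579), and the trend (-1.21, adjusted p = 0.08). Slc1a2, a glutamate transporter, rose by 1.27-fold (log2 fold change 0.34, adjusted p = 0.015), a call lost with the trend removed (0.12, adjusted p = 0.31), and Apcdd1 stood at 216 and 215 CPM (adjusted p = 0.98; log2 fold change -0.26 and adjusted p = 0.048 with the trend removed). As a set the list missed the threshold (camera adjusted p = 0.06; adjusted p = 0.82 with an estimated correlation). Once the trend was removed, 7 members fell and the set passed (camera adjusted p = 0.00044; adjusted p = 0.49 with an estimated correlation).

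Genes of the oligodendrocyte lineage went both ways. Of 15 members 3 fell and 2 rose, and 4 fell and 3 rose when adjusted over the list alone (camera adjusted p = 0.31). Olig1, a transcription factor of the lineage, fell from 25.7 ± 1.09 to 15.8 ± 3.08 CPM (-0.70, SE 0.13, adjusted p = 0.0065), in all fits that leave out a library. Bcan, the proteoglycan brevican, fell from 33.9 ± 10.3 to 10.2 ± 3.08 CPM (-1.73, SE 0.33, adjusted p = 0.027). That call was lost without control replicates 1 and 2 (adjusted p = 0.056 and 0.18) and NFIAcKO replicates 1 and 3 (0.0825 and 0.0522). Nkx2-2, a transcription factor of ventral progenitors, rose by 1.42-fold (adjusted p = 0.011) but missed the threshold without control replicate 1 (0.0543) and NFIAcKO replicates 1 and 3 (0.057 and 0.0528). In the fit without the trend 1 member of the list, Olig1, fell and 1, Nkx2-2, rose. Directions are those of the labels, which the Nfia count does not bear out.

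Genes of motor columns and pools were higher in the libraries labelled NFIAcKO, and few genes of motor neuron identity passed the test. Of the 20 column and pool genes, 7 rose and 13 did not pass, and 7 rose when adjusted over the list alone (camera adjusted p = 0.00038; adjusted p = 0.72 with an estimated correlation). Foxp1, the factor that sets limb and preganglionic motor columns, rose by 1.49-fold to 155 ± 3.71 CPM (SD, n = 3; log2 fold change 0.58, SE 0.09, adjusted p = 0.0044). It kept its call in all fits that leave out a library and with the trend removed, and it overlaps other annotated genes. In the fit without the trend 5 members rose (median 0.26, camera adjusted p = 0.0023; adjusted p = 0.503 with an estimated correlation). Among 14 motor neuron identity genes, 2 rose (Slit3 and Lhx4, each called in 1 of the 6 fits that leave out a library), 1 fell and 11 did not pass; 6 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.14). With the trend removed 1 rose and 1 fell, and the set passed (camera adjusted p = 0.049, and 0.49 with an estimated correlation). The gene that rose there was Mnx1 (adjusted p = 0.04, against 0.07 as counted), while Slit3 and Lhx4 lost their calls (0.06 and 0.056). Chat, the enzyme that makes acetylcholine, stood at 4.92 ± 0.319 and 5.74 ± 0.82 CPM (adjusted p = 0.36), and Isl1 at 53.4 ± 3.48 and 58.6 ± 3.25 CPM (adjusted p = 0.31). The member that fell was Calca, a neuropeptide gene (-1.03, SE 0.23, adjusted p = 0.012), a call lost without control replicate 1 (0.0561) and NFIAcKO replicates 1 and 3 (0.0602 and 0.0563).

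Ventral interneuron genes had the highest median of the 34 lists as counted. Of 16 tested members 7 rose and 9 did not pass, 11 rose when adjusted over the list alone, and the median was 0.43 on the log2 scale (camera adjusted p = 1.2e-05; adjusted p = 0.66 with an estimated correlation). Foxp2 rose from 58.7 ± 5.63 to 81.1 ± 2.11 CPM (SD, n = 3; 0.47, SE 0.08, adjusted p = 0.0059), in all fits that leave out a library. En1, which marks V1 interneurons, rose from 9.17 ± 1.24 to 14.4 ± 1.24 CPM (0.65, SE 0.13, adjusted p = 0.0078), with an adjusted p of 0.0515 without control replicate 1. Directions are as labelled. The list's median lay above all 10000 lists matched on length and expression. So did those of motor columns and pools and of Hox paralogs 4 to 8, and random lists do not carry the correlation between members (0.296 for ventral interneurons). With the trend removed 6 members of the ventral interneuron list rose, En1 among them and Foxp2 not (adjusted p = 0.06). Of 18 dorsal interneuron genes 4 rose, also 4 when adjusted over the list alone, and 14 did not pass (camera adjusted p = 0.086). Pax2 was the member with the smallest p and rose by 1.34-fold (adjusted p = 0.011), but missed the threshold without NFIAcKO replicates 1 and 2 (0.0507 and 0.0551).

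Genes common to neurons and genes of axon guidance were higher as sets. Of 16 pan-neuronal genes 5 rose, 1 (Uchl1) fell and 10 did not pass; 8 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.016; adjusted p = 0.66 with an estimated correlation). Without the trend 5 rose (camera adjusted p = 0.0057; adjusted p = 0.49 with an estimated correlation). Dcx, a microtubule protein of young neurons, rose from 1682 ± 182 to 2301 ± 117 CPM (SD, n = 3; adjusted p = 0.011), but missed the threshold without control replicate 1 (0.0567) and NFIAcKO replicates 1 and 3 (0.051 and 0.0628). Of 47 axon guidance genes, 20 rose, 1 (Cxcr4) fell and 26 did not pass, and 28 rose and 1 fell when adjusted over the list alone (camera adjusted p = 3.0e-08; adjusted p = 0.66 with an estimated correlation). L1cam, an adhesion molecule of axons, rose from 266 ± 32.2 to 394 ± 9.89 CPM (0.57, SE 0.09, adjusted p = 0.0046), and the semaphorin receptor Nrp2 from 288 ± 39.5 to 425 ± 9.56 CPM (0.56, SE 0.10, adjusted p = 0.0053). The receptors Plxna4 and Plxna1 rose by 1.36-fold and 1.35-fold (adjusted p = 0.0057 and 0.0072). These 4 kept their calls in all fits that leave out a library, and L1cam, Plxna4 and Plxna1 overlap other annotated genes. The list's median exonic length was 8054 bp. Once the length and GC trend was removed, 5 members rose and 1 fell, and L1cam and Nrp2 kept their calls (0.42 and 0.32), while Plxna4 and Plxna1 did not (adjusted p = 0.17 and 0.066). Of 24 synaptic and transmitter genes 5 rose, 1 (Glra2) fell and 18 did not pass, with 6 and 1 when adjusted over the list alone (camera adjusted p = 0.33). Directions are again those of the labels.

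Nuclear genes of oxidative phosphorylation fell together in the libraries labelled NFIAcKO. Of 55 tested members 39 fell and 16 did not pass, and 50 fell when adjusted over the list alone, with a median log2 fold change of -0.40 (camera adjusted p = 2.1e-15; adjusted p = 0.72 with an estimated correlation). Ndufs4, a subunit of complex I, fell from 91.1 ± 16.4 to 61.6 ± 1.38 CPM (SD, n = 3; -0.56, SE 0.11, adjusted p = 0.0075), in all fits that leave out a library. Cyc1, the cytochrome of complex III, fell by 0.48 on the log2 scale (adjusted p = 0.0083), with an adjusted p of 0.057 without NFIAcKO replicate 3. These transcripts are short, with a median exonic length of 1756 bp, and random lists matched on length and expression had a median of -0.22 (central 95% -0.28 to -0.12). After removal of the trend 14 members fell, the median was -0.18 and the set passed (camera adjusted p = 1.8e-09; adjusted p = 0.503 with an estimated correlation). Of the 7 tested mitochondrially encoded genes none was called by edgeR, DESeq2 or limma-voom, and 1 had an unadjusted p under 0.05 in edgeR, with none called when adjusted over the list alone (median 0.15, camera adjusted p = 0.16). Among fits that leave out a library, this set passed only without control replicate 2 (median 0.20, camera adjusted p = 0.031). Its median was 0.08 without NFIAcKO replicate 3. Without the trend 6 of them rose (median 0.53, camera adjusted p = 2.5e-06, and adjusted p = 0.47 with an estimated correlation). These genes are short (median exonic length 1144 bp), and removing the trend raised their values. The 6 rises rest on that removal, and whether the trend applies to mitochondrially encoded genes was not tested.

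Some genes of other metabolic lists fell as well. In the tricarboxylic acid cycle 6 of 21 genes fell, also 6 when adjusted over the list alone, and 15 did not pass (camera adjusted p = 0.042; adjusted p = 0.66 with an estimated correlation). Sdhd, a subunit of succinate dehydrogenase, fell from 106 ± 20.0 to 68.8 ± 3.19 CPM (SD, n = 3; -0.62, SE 0.11, adjusted p = 0.0073). In fatty acid oxidation 6 of 19 genes fell, 1 (Ppargc1a) rose and 12 did not pass; 7 fell and 1 rose when adjusted over the list alone (camera adjusted p = 0.042; adjusted p = 0.66 with an estimated correlation). Of 23 glycolysis genes 4 fell, 1 (Hk1) rose and 18 did not pass, the same counts when adjusted over the list alone (camera adjusted p = 0.54), and the list's median was 0.0003 while its mean and test were below 0. Pgk1 fell from 120 ± 16.9 to 81.4 ± 8.07 CPM (-0.56, SE 0.10, adjusted p = 0.007). Sdhd and Pgk1 kept their calls in all fits that leave out a library and with the trend removed. In that fit 6 genes fell in the tricarboxylic acid cycle, 1 in fatty acid oxidation and 4 in glycolysis, not all of them the genes called as counted. The tricarboxylic acid cycle set was lost without control replicate 1 and NFIAcKO replicates 1 and 3 (camera adjusted p = 0.0979, 0.0516 and 0.0599). It was also lost with Xist as a covariate (0.063) and with the replicate number as a block (0.0732). The fatty acid set was lost without control replicates 1 and 3 and NFIAcKO replicate 2 (0.0574, 0.112 and 0.0877) and with Xist as a covariate (0.0652). That set was also lost with the replicate number (0.0991) or the number shared by file names (0.0614) as a block. In cholesterol synthesis 1 of 19 genes rose (Lss; camera adjusted p = 0.69), and it was not called when adjusted over the list alone. In the pentose phosphate pathway none of 8 was called by edgeR, DESeq2 or limma-voom, with 1 at an unadjusted p under 0.05 in edgeR (camera adjusted p = 0.86).

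**Figure D3:**
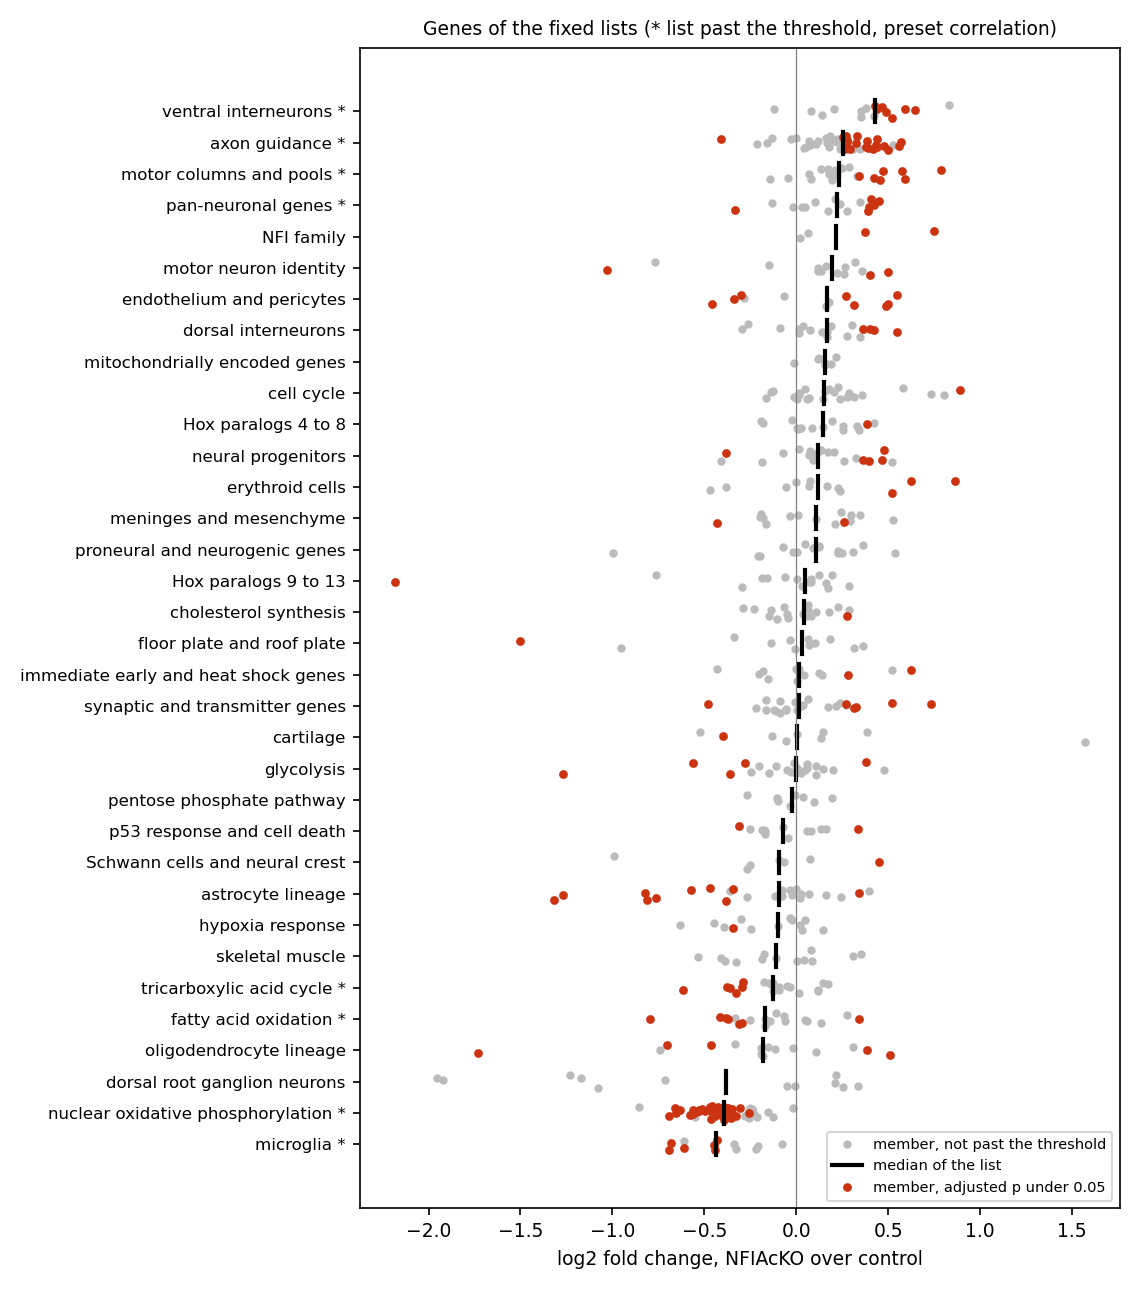
Log2 fold change (NFIAcKO over control, as labelled) of each tested member of the 34 fixed lists; points are genes, red where the adjusted p was under 0.05, and black bars are list medians. Nuclear oxidative phosphorylation has a median of -0.40 and microglia -0.44, and ventral interneurons stand at 0.43; stars mark the 8 lists past the threshold with a preset correlation.

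Progenitor, proliferation and positional genes showed few changes. Of 21 neural progenitor genes 4 rose, 1 (Hes5) fell and 16 did not pass, the same counts when adjusted over the list alone (camera adjusted p = 0.18). Of 26 cell cycle genes 1 rose, also 1 when adjusted over the list alone (camera adjusted p = 0.092). After removal of the trend the set passed (camera adjusted p = 0.036; adjusted p = 0.86 with an estimated correlation). The member called was Mki67, a marker of dividing cells, at 44.4 ± 13.1 and 82.2 ± 7.13 CPM (SD, n = 3; 0.89, SE 0.19, adjusted p = 0.023). The call was lost without every library except control replicate 3, with adjusted p of 0.0629 and 0.109 without control replicates 1 and 2 and 0.0525, 0.0608 and 0.0861 without NFIAcKO replicates 1, 2 and 3, and with the trend removed (0.0659). Among 16 proneural and neurogenic genes none was called by edgeR, DESeq2 or limma-voom, with 2 at an unadjusted p under 0.05 in edgeR (camera adjusted p = 0.52). Of 15 Hox genes of paralogs 4 to 8, Hoxc8 rose, also when adjusted over the list alone (camera adjusted p = 0.24). In the fit without the trend 3 members rose (Hoxc8, Hoxa7 and Hoxa5) and the set passed (camera adjusted p = 0.0064; adjusted p = 0.65 with an estimated correlation). Of 16 Hox genes of paralogs 9 to 13, Hoxb13 fell, though not when adjusted over the list alone, and the list had a median of 0.05 and a mean of -0.15 (camera adjusted p = 0.999). In the p53 and cell death list 1 of 13 rose (Zmat3) and 1 fell (Bax), also when adjusted over the list alone (camera adjusted p = 0.69). In the hypoxia list 1 of 13 fell (Higd1a), 2 when adjusted over the list alone (camera adjusted p = 0.16). In the list of immediate early and heat shock genes 2 of 13 rose (Egr1 and Jun), also when adjusted over the list alone (camera adjusted p = 0.49). Hoxc8, Hoxb13, Zmat3, Bax, Higd1a, Egr1 and Jun each lost the call in at least 2 of the 6 fits that leave out a library.

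Microglial genes were lower in the libraries labelled NFIAcKO, and endothelial genes went both ways as counted. Of 12 tested microglial genes 6 fell and 6 did not pass, and 9 fell when adjusted over the list alone, with a median log2 fold change of -0.44 (camera adjusted p = 9.7e-06; adjusted p = 0.58 with an estimated correlation). The complement gene C1qc fell from 16.5 ± 1.89 to 10.8 ± 1.43 CPM (SD, n = 3; -0.61, SE 0.13, adjusted p = 0.01; 0.0587 without control replicate 1). Without the trend, 2 microglial genes fell, C1qc among them (median of the list -0.32, camera adjusted p = 2.3e-05; adjusted p = 0.47 with an estimated correlation). Of 12 endothelial and pericyte genes 5 rose and 3 fell, with 5 and 4 when adjusted over the list alone (camera adjusted p = 0.45). The endothelial cadherin Cdh5 rose from 64.4 ± 10.7 to 94.3 ± 4.41 CPM (0.55, SE 0.10, adjusted p = 0.0073), in all fits that leave out a library. With the trend removed 2 members of the endothelial and pericyte list rose and 0 fell. Of 12 erythroid genes 3 rose, also 3 when adjusted over the list alone (camera adjusted p = 0.24), and with the trend removed the set passed (camera adjusted p = 0.009; adjusted p = 0.49 with an estimated correlation). The embryonic globin gene Hba-x rose from 147 ± 6.11 to 211 ± 19.6 CPM (0.52, SE 0.09, adjusted p = 0.0046). Directions here too are those of the labels.

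Other marker lists gave few calls. Among 12 floor plate and roof plate genes Wnt3a fell, also when adjusted over the list alone (camera adjusted p = 0.997; median 0.03, mean -0.16, test above 0). Among 7 Schwann cell and neural crest genes Tfap2b rose, also when adjusted over the list alone (camera adjusted p = 0.73). Among 15 genes of meninges and mesenchyme Pdgfrb rose and Slc6a13 fell, also when adjusted over the list alone (camera adjusted p = 0.69). Among 9 cartilage genes Col9a3 fell, also when adjusted over the list alone (camera adjusted p = 0.85; median 0.01, mean 0.13, test below 0). None of 12 dorsal root ganglion genes and none of 13 skeletal muscle genes was called by edgeR, DESeq2 or limma-voom (camera adjusted p = 0.85 and 0.71). In edgeR, 2 of the ganglion genes and 0 of the muscle genes had an unadjusted p under 0.05. The ganglion list had a median log2 fold change of -0.38, but 1 library turned its sign: it was -0.62 without control replicate 1 and 0.18 without control replicate 3. The floor and roof plate and cartilage medians turned sign too. They were -0.12 and -0.08 without control replicate 2, and 0.25 and 0.26 without control replicate 3. Wnt3a, Tfap2b, Pdgfrb, Slc6a13 and Col9a3 each lost the call in at least 4 of the 6 fits that leave out a library.

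Among the 10 largest rises by the rule for named genes, Onecut1, Onecut2 and Dchs2 kept their calls in all fits that leave out a library. Onecut2, a transcription factor of developing neurons, rose from 24.1 ± 2.78 to 44.4 ± 1.21 CPM (SD, n = 3; 0.88, SE 0.10, adjusted p = 0.0008), and lies on chromosome 18 of GRCm38 from 64340020 to 64400987. Onecut1 rose from 3.93 ± 0.859 to 7.34 ± 0.198 CPM (0.90, SE 0.17, adjusted p = 0.0065), a value made uncertain by Gm20649, which overlaps 2171 bp of it on the same strand. Dchs2, a large cadherin that Gm10710 overlaps on the opposite strand, rose by 1.82-fold (adjusted p = 0.0043), and Fbn2, fibrillin 2, by 1.85-fold (adjusted p = 0.0069; 0.0923 without control replicate 2). These 4 also rose with the trend removed. The others of the 10 were Lmntd1, Vmn2r57, Myh7b, Cubn, Mki67 and Epb42, which rose by 2.38-fold, 2.05-fold, 1.97-fold, 1.91-fold, 1.85-fold and 1.82-fold, and each lost its call in at least 4 of the 6 fits that leave out a library. Their highest adjusted p in these fits was 0.0986 for Lmntd1 and 0.178 for Myh7b (without NFIAcKO replicate 1), 0.17 for Vmn2r57 (without NFIAcKO replicate 3), 0.132 for Cubn and 0.162 for Epb42 (without control replicate 1), and 0.109 for Mki67 (without control replicate 2). Among the 10 largest falls, Ramp1, Cmtm5, Rlbp1 and Rgcc kept their calls in all 6 of these fits and with the trend removed. Rlbp1, a retinaldehyde-binding protein of glia, fell from 22.4 ± 5.93 to 9.06 ± 0.733 CPM (-1.31, SE 0.17, adjusted p = 0.0031), and lies on chromosome 7 from 79374870 to 79387048. Ramp1, a subunit of the receptor for calcitonin gene-related peptide, fell from 2.17 ± 0.964 to 0.394 ± 0.0556 CPM (-2.45, SE 0.36, adjusted p = 0.0042). Cmtm5 and Rgcc fell by 1.95 and 1.30 on the log2 scale (adjusted p = 0.0072 and 0.0046). The others were n-R5-8s1, a ribosomal RNA gene, Hoxb13, Bcan, Bambi-ps1, Scn7a and S100b, with log2 fold changes of -3.95, -2.18, -1.73, -1.39, -1.37 and -1.32, and each lost its call in at least 3 of the 6 fits. Their highest adjusted p was 0.125 for n-R5-8s1 and 0.0809 for Bambi-ps1 (without NFIAcKO replicate 1), and 0.182 for Hoxb13, 0.18 for Bcan, 0.33 for Scn7a and 0.161 for S100b (without control replicate 2). Without that library Scn7a stood at -0.68 and n-R5-8s1 at -2.50. Directions follow the labels, which the Nfia count does not bear out.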

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

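Removing the length and GC trend was chosen after the data were seen; the other alternatives were fixed beforehand. Against 1392 genes higher and 1076 lower in the libraries labelled NFIAcKO, the counts were 1900 and 1406 with DESeq2 and 1377 and 963 with limma-voom, and other scalings, filters and covariates kept both within 1.5 times. A test against a fold change of 1.2 gave 27 and 14, which asks for a larger change. With the trend removed they were 676 and 686; the cause was not tested here. Leaving out each library gave 282 to 2703 higher and 139 to 2466 lower. Fewer samples do not explain the 2703 and 2466 calls without control replicate 3, which on the first principal component (0.828) lay between the other controls (-21.9 and -40.3) and the libraries labelled NFIAcKO (19.5 to 21.1); why it lay there was not tested. Of 34 lists, 8 passed, 14 with the trend removed and 0 with an estimated correlation (2 at an unadjusted p under 0.05), and 7 to 11 when a library was left out. Nfia stayed higher and past the threshold in the 17 alternatives for which its value was kept, with an adjusted p of up to 0.0413 (without control replicate 1). Its value in the test against a fold change of 1.2 was not kept, so Nfia is left out of the count for that test below. No call among the 152 named genes changed direction. Of the 98 past the threshold, 39 missed it with the trend removed, 90 against a fold change of 1.2, 57, 45 and 3 without control replicates 1, 2 and 3, and 66, 49 and 58 without NFIAcKO replicates 1, 2 and 3.

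The replicate block, with the numbers in the titles as a factor, gave 1353 genes higher, 1119 lower and 6 lists, with the tricarboxylic acid cycle and fatty acid oxidation lists at an adjusted p of 0.0732 and 0.0991. Deviations from the group means correlated by 0.0875, 0.12 and 0.119 between libraries of the same number and by -0.0894 to -0.0369 between others. Every library thus correlated best with its own number, but this cannot decide whether the numbers pair the libraries. Deviations sum to 0 within a group, so positive covariances within numbers force negative ones across numbers. Replicate 2 was also the Xist-expressing library of both groups, so shared sex cannot be told apart from a shared number there. The labels do not say what the numbers share. Depth was similar in all libraries; at it, simulated 1.5-fold changes were missed in part, as 61% were recovered.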

Other observations

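The tests here were chosen after the results were seen, except the count of other splits. Genes of ribosomal proteins, looked at after the data were seen, fell in large part in the libraries labelled NFIAcKO. Of 83 tested genes 61 fell and the rest did not pass in edgeR, with a median log2 fold change of -0.47, and 40 fell with the length and GC trend removed (median -0.28). Random lists matched on length and expression had a median of -0.16 (central 95% -0.24 to -0.08). Their share of all counts was 2.67 ± 0.363% (SD, n = 3) in the libraries labelled control and 1.91 ± 0.0957% in those labelled NFIAcKO. Rpl22l1 fell from 23.7 ± 5.5 to 11.5 ± 1.51 CPM (adjusted p = 0.0044) and Rps27 from 248 ± 47.3 to 150 ± 14.1 CPM (adjusted p = 0.0057).

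Several single genes outside the fixed lists, named after their values were seen, changed as strongly as the listed ones. They were taken from genes called both as counted and with the trend removed, so keeping the call is no separate support. Timp4, an inhibitor of metalloproteinases, fell from 10.1 ± 1.63 to 4.39 ± 0.664 CPM (log2 fold change -1.21, SE 0.16, adjusted p = 0.0025). Cbs, the cystathionine synthase, fell from 9.33 ± 2.07 to 4.22 ± 0.721 CPM (adjusted p = 0.0044), and the transaminase Gpt2 from 95.7 ± 13.9 to 60.7 ± 0.635 CPM (adjusted p = 0.004). Otp, a homeodomain factor of interneurons, rose from 151 ± 21.1 to 228 ± 16.3 CPM (adjusted p = 0.0048). Map1b, a microtubule protein of growing axons, rose from 1411 ± 193 to 2499 ± 233 CPM (adjusted p = 0.0025).

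Long transcripts were higher and short ones lower in the libraries labelled NFIAcKO, by 0.13 on the log2 scale per doubling of length over 13040 genes (SE 0.00207). Each SE of a slope here is over genes, so it does not measure the spread between embryos. Slopes of single libraries, relative to the mean of the libraries, averaged -0.0667 (SD 0.049, n = 3) in those labelled control. In those labelled NFIAcKO they averaged 0.0667 (SD 0.0268, n = 3). Among 62 marker genes of other cell types (such as vessels, meninges, microglia and ganglion neurons) the slope was 0.1966 (SE 0.0476), and 0.165 (SE 0.048) over 33 genes without microglia, Schwann cells, floor and roof plate and ganglion neurons. Both lie above 0 by over 2 SE over genes, which a higher share of neuronal RNA as the whole cause does not predict. A length bias of the libraries predicts it and may contribute, as the slope was also above 0 in pan-neuronal and synaptic genes (0.106, SE 0.0438). It was not above 0 by 2 SE in 79 ribosomal protein genes (0.0263, SE 0.0254). In metabolism lists the slope was 0.164 (SE 0.0176). Those lists hold the short nuclear genes of oxidative phosphorylation, so this slope may restate their fall and is not separate support. The trend with summed exonic length and GC alone does not account for the calls, as 39.59% kept call and direction when it was removed. The length of the transcripts that were expressed was not used, so a length bias as the whole cause cannot be decided this way. RNA integrity and library batch are not given in the labels used here, and a change of transcription by genotype that follows length stays open and untested. The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05: 1 split, the real one, gave 2468 genes, and the highest other gave 1.

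Nfia was higher where the label says that it was deleted, and exchanged group labels would put astrocyte genes up in the libraries labelled NFIAcKO, given the textbook role of NFIA in gliogenesis. The median log2 fold change of the 24 tested members was -0.09625 (SE 0.119 over members), and -0.19 (SE 0.10) with the trend removed, both within 2 SE of 0. With 1 library left out the median was -0.0845 to -0.178. The set then passed, lower, without control replicates 2 and 3 and NFIAcKO replicate 1 (camera adjusted p = 0.0409, 0.0334 and 0.0355). It missed the threshold without control replicate 1 and NFIAcKO replicates 2 and 3 (0.143, 0.128 and 0.0599). The mean (-0.27, SE 0.09), 9 of 10 calls and the set with the trend removed (camera adjusted p = 0.00044; adjusted p = 0.49 with an estimated correlation) go against exchanged labels, which stay open as the set missed the threshold as counted and with an estimated correlation. The trend with summed exonic length and GC as the whole cause is argued against by a log2 fold change of 0.6179 (SE 0.0964) once it was removed. Open and untested here is whether the remaining exons are transcribed at a higher rate or kept longer as RNA, since counts per exon were not analysed here.

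Of 55 nuclear genes of oxidative phosphorylation 39 fell and 16 did not pass (camera adjusted p = 2.1e-15; adjusted p = 0.72 with an estimated correlation), and their short transcripts may explain part of this. Their median of -0.3956 lay below all 10000 medians of random lists matched on summed exonic length and expression (median -0.22). This argues against summed exonic length as the whole cause, though random lists do not carry the correlation between members (0.784). The length of the transcripts that were expressed was not matched, so short transcripts as the whole cause cannot be decided this way. The median went to -0.18 with the trend removed, and ribosomal protein genes, which are also short, fell as well. A change by genotype stays open, and a difference in RNA handling between the groups was not tested.

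A hypothesis of a shift from late-born toward early-born neuron programs was tested with 7 early factors (Onecut1, Onecut2, Onecut3, Pou2f2, Zfhx2, Zfhx3 and Zfhx4) and 5 late ones (Neurod2, Neurod6, Tcf4, Nfib and Nfix), a late list without Nfia. All 7 early factors rose in edgeR, and 6 with the trend removed. Zfhx3 was higher by 0.83 on the log2 scale as counted (SE 0.09, adjusted p = 0.0008) and by 0.44 with the trend removed (SE 0.07, adjusted p = 0.009). The early factor that lost its call was Zfhx2, at 0.57 as counted and 0.16 with the trend removed (adjusted p = 0.14). The test was chosen after the results were seen, and Onecut1 and Onecut2 were already among the largest rises named above. The rise of the early factors, and the score that rests on it, is therefore no separate support for the shift. With the trend removed the early minus late score was higher by 0.5253 in the libraries labelled NFIAcKO, with no overlap between groups (two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). The late factors went both ways in that fit, with a mean of -0.02 (SE 0.11), or 0.09 (SE 0.14) with Nfia added: Neurod6 rose (0.34, adjusted p = 0.047, against 0.09 and adjusted p = 0.57 as counted), while Neurod2, Tcf4, Nfib and Nfix stood at 0.12, -0.20, -0.16 and -0.19 and did not pass (adjusted p = 0.27, 0.13, 0.23 and 0.28). This neither shows nor excludes the fall of late programs that the hypothesis needs, so the shift stays open, and the rise of the early factors may also be a change of its own.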
